A study of Mus musculus with 42 samples.

How the data were processed

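Gene expression was measured in spleens of female BALB/c mice with 2-colour oligonucleotide arrays in a reference design. Per the labels, spleen RNA was extracted with TRIzol and its cDNA labelled with Cy5, and cDNA of a universal mouse reference RNA, a mix from several tissues and cell types, was labelled with Cy3 and hybridised to the same array. The CpG mixture held the ODN 1555 and 1466 and the control mixture the ODN 1612 and 1471, in equal molar amounts and 400 µg in all. The deposited values are log2 ratios of sample over reference for 30601 features on 42 arrays, as the authors made them. The log base, the normalization within arrays and the spot filter are not given in the sources used here. Base 2 was inferred from the range (-6.86 to 9.78), and the arrays are centred, with medians from -0.014 to 0.019. The direction was inferred from untreated spleens (mean ± SD, n = 6), where spleen genes were high (Cd79a 5.64 ± 0.55, Hbb-b1 6.83 ± 0.78, H2-Aa 6.79 ± 0.12) and Ptgs2 -4.79 ± 0.40, Cxcl1 -4.19 ± 0.26 and Fn1 -3.80 ± 0.28 were low. If the base were another, every log2 difference would scale by 1 factor and the tests would stay.

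Features were paired with genes through the annotation table of the array. A gene's value is the mean over the features with its symbol alone: 23485 features gave 15277 genes, 5163 of them with more than 1 feature, while 179 features with several symbols and 6937 without one were left out of the gene tests. Genes are named by symbol, and positions were not used. Correlations between arrays ran from 0.746 to 0.978 over 861 pairs, and 0 pairs were identical. Array SD ran from 0.983 to 1.2, and signal over background was not used here.

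Differences between groups were tested with limma 3.58.1 in R 4.3.3, in 1 fit of all 42 arrays with 1 coefficient per group and empirical Bayes spread. A gene was tested where at least 3 arrays of each group had a value, and called at an adjusted p below 0.05 (Benjamini-Hochberg within a comparison, 2-sided). Comparisons were each of the 8 CpG times and control ODN against untreated, CpG against control ODN at 3 h, and CpG 5 days against 72 h, with limma's F test over the 8 CpG times. The ± after a difference is the standard error of the fit.

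The 25 gene lists were interferon-stimulated genes, interferon-gamma GTPases and antigen processing, inflammatory cytokines, chemokines, NF-kB targets and feedback, Toll-like receptor pathway, SOCS and DUSP feedback, macrophage activation effectors, complement, mitotic cell cycle, DNA replication, DNA repair, ribosomal proteins, and markers of B cells, plasma cells, T cells, NK and cytotoxic cells, neutrophils and myeloid granules, monocytes and macrophages, dendritic cells, erythroid cells, megakaryocytes and platelets, endothelial cells and fibroblasts, pancreas acinar cells and adipocytes. They were written from general knowledge and tested with limma's cameraPR at a preset correlation of 0.01, adjusted over the lists within a comparison. The same lists were tested with camera at an estimated correlation and with fry, on genes measured on all arrays. Tests of lists between times used the preset correlation alone. Counts of members are given over all genes tested and adjusted over the list alone.

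Genes were named by a rule. Its first part took called genes measured on all arrays of both groups, whose groups did not overlap and whose tested features all went 1 way: the 10 highest and 10 lowest for CpG 3 h against untreated, 8 and 8 for 9 h, 24 h, 5 days and CpG against control ODN, and 5 and 5 otherwise, passing over clone and predicted-gene symbols. Its other parts took up to 4 called members of each list with the largest difference, and a panel of 20 genes given whatever the result. Of these 2 are not reported here. Groups, comparisons, tests, lists, the rule and most alternatives were chosen before the data were examined. The alternatives with the acinar mean as covariate, without arrays with over 1000 missing values and with runs as a fixed block on genes measured on all arrays were chosen after seeing the data.

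Alternatives changed centring, scaling between arrays, the filter on missing values, the unit (single features), the spread, array weights, the arrays fitted, thresholds and blocks by replicate number and by run, and left out each array in turn. Runs are arrays whose database numbers in the titles lie within 12 of the next, which gave 10 runs, 4 with 1 array. Other splits of the same arrays were fitted, 100 drawn or all 35. On simulated data with 200 changed genes in the layout of CpG 3 h against untreated, the test recovered 26.9%, 77.6% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 6 false among 148 calls. These include members of the mitotic list, raised by 0.5 as well. In that of 5 days against 72 h it recovered 19.4%, 79.1% and 100%, with 4 false among 139. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.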

Results

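Spleen RNA from female BALB/c mice was measured on 42 arrays that fall into 10 groups. The mice were given an intraperitoneal injection of 400 µg of CpG oligodeoxynucleotides (CpG ODN), which engage the endosomal receptor TLR9, or of control oligodeoxynucleotides (control ODN), or were left untreated. Spleens of CpG-treated mice were taken after 3 h, 9 h, 24 h and 72 h and after 5, 7, 9 and 14 days, and those of mice given control ODN after 3 h. The untreated group had 6 arrays and each other group 4, described in the series as independent biological replicates. Each array compared spleen cDNA with a common mouse reference cDNA, so every value is a log2 ratio of sample over reference (the log base and the direction are inferred from the values). The arrays carried 30601 features, and 23485 of them with a single gene symbol gave 15277 genes, 12588 with a value on every array. Between 173 and 1740 features had no value on an array, and the number of arrays limits the precision of every difference. Differences are given as log2 difference ± standard error, from 4 arrays against 6 for each comparison with the untreated group and 4 against 4 otherwise. Counts for a list are over its measured members, and its median is that of their log2 differences. Where a list lost its call with an estimated correlation between its genes, on genes measured on all arrays, that adjusted p is given too. Other list calls held unless stated.

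**Figure D1:**
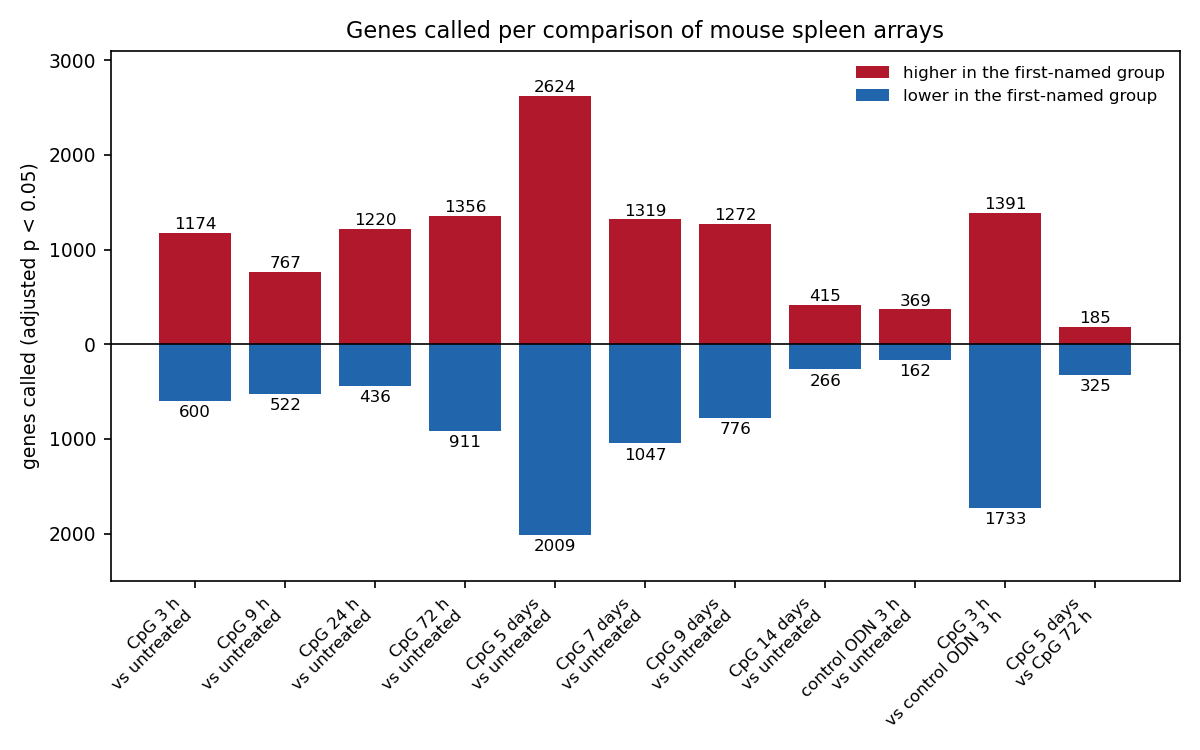
Number of genes called higher (bars above 0) and lower (bars below) in each of the 11 comparisons. The 5 day group differed from untreated in 4633 genes and the 14 day group in 681.

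The comparison of CpG 3 h with untreated spleens asks for the short-term response to the injection. By 3 h the spleens held far more transcripts of the interferon response and of chemokines that draw in monocytes and lymphocytes. The highest genes were Ccl12 (4.81 ± 0.31), Ifit2 (4.57 ± 0.21), Ifi204 (4.46 ± 0.21) and Cxcl10 (4.46 ± 0.30), a monocyte chemokine, an interferon-induced antiviral protein, a member of the interferon-inducible p200 family and a T cell chemokine. Ifit3 (4.44 ± 0.28), Ccl4 (4.38 ± 0.21) and Usp18 (4.01 ± 0.24) followed, the last being the protease that removes ISG15 from proteins, together with the formyl peptide receptor gene Fpr2 (4.10 ± 0.75), Phf11d (4.01 ± 0.19) and Impg2 (4.07 ± 0.22). The lowest genes included Slc40a1, which encodes the iron exporter ferroportin (-2.66 ± 0.21), Tcf21, a transcription factor needed for spleen development (-2.63 ± 0.24), Pcdh18 (-2.46 ± 0.39) and Id4 (-2.41 ± 0.31) and the metabolic enzymes Gpd1 (-2.20 ± 0.24) and Hpgd (-2.19 ± 0.26). Gas1 (-2.10 ± 0.20), Tmem273 (-2.02 ± 0.15), Arvcf (-1.98 ± 0.23) and Cmbl (-1.90 ± 0.23) were the other genes of the lowest 10. The largest adjusted p among these 20 genes was 9.16e-05, and for each of them every treated array lay beyond every untreated array.

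Among interferon-stimulated genes 25 of 25 members rose, 25 adjusted over the list alone (median 2.30, adjusted p = 4.52e-123). The list mean stood at 3.21 ± 0.18 (SD, n = 4) against 0.76 ± 0.13 (SD, n = 6) in untreated spleens. Of the interferon-gamma GTPases and antigen processing genes 17 of 21 members rose, 19 adjusted over the list alone (median 1.41, adjusted p = 1.9e-30), with Gbp2 (3.44 ± 0.26), Gbp6 (2.93 ± 0.21) and Iigp1 (2.93 ± 0.25) at the top. Targets and feedback inhibitors of NF-kB moved with them, and 17 of 22 members rose, 21 adjusted over the list alone (median 1.22, adjusted p = 7.65e-35). They included Nfkbiz (3.66 ± 0.15), Gadd45b (3.05 ± 0.22) and Tnfaip3 (2.42 ± 0.19), of which the first encodes an atypical IκB protein and the last the ubiquitin-editing inhibitor A20. Of the inflammatory cytokines 11 of 23 members rose, 12 adjusted over the list alone (median 0.54, adjusted p = 9.25e-19), led by Il12b, the p40 subunit of IL-12 and IL-23 (3.67 ± 0.18), Il6 (3.30 ± 0.29), Tnf (2.25 ± 0.22) and Il15 (1.96 ± 0.17). Of the chemokines 13 of 25 members rose and 1 fell, 15 and 1 adjusted over the list alone (median 0.76, adjusted p = 7.36e-20). Macrophage activation effectors included the collagenase gene Mmp13 (3.04 ± 0.19), Acod1, whose enzyme makes itaconate (2.72 ± 0.23), and the acute-phase gene Saa3 (1.97 ± 0.25), and 11 of 21 members rose, 12 adjusted over the list alone (median 0.57, adjusted p = 1.42e-14).

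In the Toll-like receptor pathway list 9 of 28 members rose, 9 adjusted over the list alone (median 0.13, adjusted p = 0.000373, adjusted p = 0.234 with an estimated correlation). Its members included the co-receptor gene Cd14 (3.38 ± 0.25), Tlr2 (2.00 ± 0.25) and Tlr7 (1.49 ± 0.24) and the adaptor gene Myd88 (1.42 ± 0.19). In the SOCS and DUSP feedback list 4 of 19 members rose, 5 adjusted over the list alone (median 0.17, adjusted p = 0.000373, adjusted p = 0.201 with an estimated correlation), with Socs3 (3.32 ± 0.27), Dusp1 (2.07 ± 0.30) and Socs1 (1.99 ± 0.18). Of the neutrophil and myeloid granule markers 7 of 21 members rose, 8 adjusted over the list alone (median 0.24, adjusted p = 0.00886, adjusted p = 0.473 with an estimated correlation), with Mmp8, the neutrophil collagenase (2.94 ± 0.38), and Lcn2, a binder of bacterial siderophores (2.64 ± 0.32). Of the 31 mitotic cell cycle genes 0 passed limma's test, 4 had an unadjusted p below 0.05, and the list was lower (median -0.26, adjusted p = 0.0431, adjusted p = 0.716 with an estimated correlation). Markers of other cell types moved singly: the cytotoxic granule protease gene Gzmb rose (2.84 ± 0.30), as did the dendritic cell genes Id2 and Ly75 (1.42 ± 0.14 and 1.06 ± 0.16), the adhesion receptor gene Selp (1.69 ± 0.18) and the complement gene Cfb (1.09 ± 0.22), while Cd79b, part of the B cell receptor, fell (-0.90 ± 0.15).

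In all, 1774 of 15253 genes tested differed, 1174 higher and 600 lower, and the groups did not overlap for 1940 of 14214 genes measured on all their arrays (13.6%, chance 0.952%). The arrays fall into runs of database numbers, inferred from the sample titles. Fitting the runs as a fixed block on genes measured on all arrays, which rests on 1 untreated array in a run with CpG 3 h arrays, called 392 genes (1601 on the same genes without the block), 382 of them among the 1774, while array weights gave 2678.

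At 9 h interferon-stimulated genes were high, together with the monocyte gene Ms4a6d. At the top stood Ms4a6d (4.74 ± 0.22) and Ccl12 (4.69 ± 0.31), the schlafen genes Slfn4 (4.32 ± 0.31) and Slfn3 (3.73 ± 0.25), Ifit3 (4.06 ± 0.28), Ifit2 (3.99 ± 0.21) and Phf11d (3.74 ± 0.19) and the endothelial lipase gene Lipg (3.74 ± 0.35). The lowest were the mannose receptor gene Mrc1 (-2.32 ± 0.40), Naaa (-1.98 ± 0.20), Ccl24 (-1.89 ± 0.17) and Cadm1 (-1.83 ± 0.17), Slc15a2 (-1.81 ± 0.26), Abcc3 (-1.80 ± 0.23), Kazald1 (-1.79 ± 0.27) and Igfbp5 (-1.79 ± 0.26). Adjusted p was at most 6.21e-05 for these genes.

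Of the interferon-stimulated genes 25 of 25 members rose, 25 adjusted over the list alone (median 2.18, adjusted p = 3.58e-133). Of the interferon-gamma GTPases and antigen processing genes 19 of 21 members rose, 20 adjusted over the list alone (median 1.22, adjusted p = 2.1e-37). In the cytokine list 10 of 23 members rose, 11 adjusted over the list alone (median 0.39, adjusted p = 1.47e-11), with Il12b (2.82 ± 0.18), the anti-inflammatory cytokine gene Il10 (1.83 ± 0.20) and Il6 (1.72 ± 0.29). Of the chemokines 12 of 25 members rose and 2 fell, 13 and 3 adjusted over the list alone (median 0.72, adjusted p = 2.53e-09), among them Cxcl10 (2.92 ± 0.30) and Cxcl9 (2.75 ± 0.36). Of the macrophage activation effectors 8 of 21 members rose, 9 adjusted over the list alone (median 0.32, adjusted p = 8.71e-11), and of the NF-kB targets 9 of 22 members rose, 10 adjusted over the list alone (median 0.43, adjusted p = 4.77e-10). Of the neutrophil and myeloid granule markers 8 of 21 members rose, 11 adjusted over the list alone (median 0.67, adjusted p = 1.03e-09), led by Lcn2 (3.34 ± 0.32), Mmp8 (2.93 ± 0.38) and Chil3 (1.86 ± 0.32).

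T cell markers were lower as a list: 5 of 21 members fell, 10 adjusted over the list alone (median -0.46, adjusted p = 2.92e-06, adjusted p = 0.0824 with an estimated correlation). They included the CD3 chain gene Cd3g (-0.90 ± 0.18), Trat1 (-0.83 ± 0.18) and the co-stimulatory receptor gene Cd28 (-0.80 ± 0.17). Of the B cell markers 3 of 21 members fell, 3 adjusted over the list alone (median -0.27, adjusted p = 0.0267, adjusted p = 0.499 with an estimated correlation), with H2-Ob (-1.30 ± 0.28) and Cd79b (-0.65 ± 0.15) among them. The lists for mitotic cell cycle and DNA replication were lower, and those for the Toll-like receptor pathway and NK and cytotoxic cells higher, with adjusted p from 0.00146 to 0.0267 and adjusted p from 0.367 to 0.595 with an estimated correlation. For SOCS and DUSP feedback the median was at 0 within rounding and the mean at 0.25, and the list was not called (adjusted p = 0.0672). In all, 1289 of 15129 genes tested differed, 767 higher and 522 lower, with no overlap between the groups for 1249 of 14063 genes measured on all their arrays (8.88%, chance 0.952%). With the runs as a fixed block on genes measured on all arrays 142 were called (1151 without the block), on the same single untreated array as at 3 h.

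At 24 h Ms4a6d (3.95 ± 0.22), Slfn4 (3.12 ± 0.31), Ifi44l (3.09 ± 0.31) and Ccl12 (3.05 ± 0.31), the GTPase gene Iigp1 (3.02 ± 0.25), Phf11d (3.00 ± 0.19) and Cd5l, which encodes a secreted macrophage protein (2.98 ± 0.44), were among the highest 8, with Reg3a, an antibacterial lectin gene, at 3.76 ± 0.96. Without CpG 24 h replicate 3 Reg3a stood at 2.92 with adjusted p = 0.0824. The lowest 8 held the water channel gene Aqp1 (-1.83 ± 0.29), Crisp3 (-1.75 ± 0.27) and Fn3k (-1.73 ± 0.33), the mitochondrial iron importer gene Slc25a37 (-1.72 ± 0.28), Fech, the last enzyme of haem synthesis (-1.59 ± 0.31), Cd207 (-1.56 ± 0.27) and Mgst3 (-1.53 ± 0.32) and the proliferation marker Mki67 (-1.49 ± 0.41). Without CpG 24 h replicate 3 Mki67 stood at -1.43 with adjusted p = 0.053. Apart from Reg3a and Mki67, adjusted p was at most 0.00121.

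Of the erythroid markers 9 of 27 members fell, 17 adjusted over the list alone (median -0.73, adjusted p = 2.87e-09, adjusted p = 0.198 with an estimated correlation). The list mean was 2.46 ± 0.31 (SD, n = 4) against 3.14 ± 0.17 (SD, n = 6). Among interferon-stimulated genes 22 of 25 members rose, 23 adjusted over the list alone (median 1.40, adjusted p = 9.49e-63). Of the interferon-gamma GTPases and antigen processing genes 16 of 21 members rose, 16 adjusted over the list alone (median 1.11, adjusted p = 1.51e-25). Among monocyte and macrophage markers 6 of 23 members rose, 6 adjusted over the list alone (median 0.28, adjusted p = 1.6e-05, adjusted p = 0.198 with an estimated correlation), with Cd5l (2.98 ± 0.44) and Ly6c1 (2.14 ± 0.21) and the scavenger receptor gene Msr1 (1.76 ± 0.15). Of the complement genes 5 of 15 members rose, 6, and 1 fell, adjusted over the list alone (median 0.43, adjusted p = 0.00361, adjusted p = 0.359 with an estimated correlation), with Cfb (1.95 ± 0.22), C1qc (1.32 ± 0.25) and C2 (1.24 ± 0.19). Of the inflammatory cytokines 8 of 22 members rose, 8 adjusted over the list alone (median 0.31, adjusted p = 0.000771, adjusted p = 0.0975 with an estimated correlation), with Il18 (1.65 ± 0.21) and Il1a (1.38 ± 0.27).

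Neutrophil, NK, chemokine, ribosomal protein and Toll-like receptor lists were also called higher, and the T cell and mitotic lists lower, with adjusted p from 0.000508 to 0.0411 and adjusted p from 0.407 to 0.626 with an estimated correlation. Members that rose included Gzmb (2.54 ± 0.30), Gzma (1.32 ± 0.29) and Mmp8 (2.08 ± 0.38). Of the ribosomal proteins 8 of 48 members rose (8 adjusted over the list alone), with a median of 0.10. In all, 1656 of 15190 genes tested differed, 1220 higher and 436 lower, with no overlap for 1144 of 14134 genes measured on all their arrays (8.09%, chance 0.952%). Without CpG 24 h replicate 3 the count was 832, and without replicate 4 it was 2572. The fit with runs as a fixed block on genes measured on all arrays called 133 (1540 without the block), and a fit of these 10 arrays alone 1070.

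By 72 h the highest genes were Apol10a (3.64 ± 0.40), the guanylate-binding protein gene Gbp2b (3.37 ± 0.27), Iigp1 (3.04 ± 0.25), Ms4a6d (2.99 ± 0.22) and Cd5l (2.74 ± 0.44). The lowest were the macrophage elastase gene Mmp12 (-1.49 ± 0.20), Cbx7 (-1.42 ± 0.25) and Retreg1 (-1.28 ± 0.19), the chemokine receptor gene Cxcr4 (-1.19 ± 0.24) and Aff4 (-1.16 ± 0.21). The largest adjusted p of these genes was 0.000844. Of the interferon-gamma GTPases and antigen processing genes 16 of 21 members rose, 17 adjusted over the list alone (median 1.45, adjusted p = 3.64e-32). Of the interferon-stimulated genes 21 of 25 members rose, 24 adjusted over the list alone (median 1.18, adjusted p = 6.54e-39), with Ifit1 (2.30 ± 0.17), Oasl2 (2.27 ± 0.17) and Usp18 (2.04 ± 0.24).

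Of the mitotic cell cycle genes 23 of 31 members rose, 24 adjusted over the list alone (median 0.83, adjusted p = 2.23e-11, adjusted p = 0.167 with an estimated correlation), with the spindle checkpoint kinase gene Bub1 at 1.25 ± 0.24. Of the DNA replication genes 15 of 38 members rose, 22 adjusted over the list alone (median 0.53, adjusted p = 3.86e-09, adjusted p = 0.167 with an estimated correlation), with the primase gene Prim2 (1.43 ± 0.29) and the helicase factor gene Cdc45 (1.00 ± 0.25). Among NK and cytotoxic markers 7 of 17 members rose, 9 adjusted over the list alone (median 0.81, adjusted p = 2.03e-06, adjusted p = 0.167 with an estimated correlation), with Gzmb (2.60 ± 0.30), Nkg7 (1.09 ± 0.26) and Klrk1 (1.03 ± 0.17). Of the T cell markers 1 of 21 members rose and 8 fell, 1 and 9 adjusted over the list alone (median -0.46, adjusted p = 2.03e-06, adjusted p = 0.16 with an estimated correlation), the fallen members including Lef1 (-1.13 ± 0.18) and Cd3e (-0.95 ± 0.17). Of the B cell markers 6 of 21 members fell, 7 adjusted over the list alone (median -0.35, adjusted p = 1e-05, adjusted p = 0.16 with an estimated correlation), with Cd79b (-0.94 ± 0.15) and the B lineage factor gene Pax5 (-0.76 ± 0.17). Monocyte and macrophage markers were higher (median 0.41, adjusted p = 2.03e-06, adjusted p = 0.126 with an estimated correlation). Neutrophil, erythroid, DNA repair, megakaryocyte and complement lists were also called higher (adjusted p from 1e-05 to 0.00384), with adjusted p from 0.16 to 0.255 with an estimated correlation. Primary granule genes were among the neutrophil markers that rose, with Ctsg (2.09 ± 0.34), Prtn3 (1.61 ± 0.30) and Mpo (1.41 ± 0.26).

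In all, 2267 of 15161 genes tested differed, 1356 higher and 911 lower, with no overlap for 1645 of 13957 genes measured on all their arrays (11.8%, chance 0.952%). Without CpG 72 h replicate 2 the count was 1225, without replicate 3 it was 1126, and without arrays with over 1000 missing values 878, while array weights gave 5639. No untreated array shares a run with the 72 h arrays, so run and group cannot be told apart here.

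**Figure D2:**
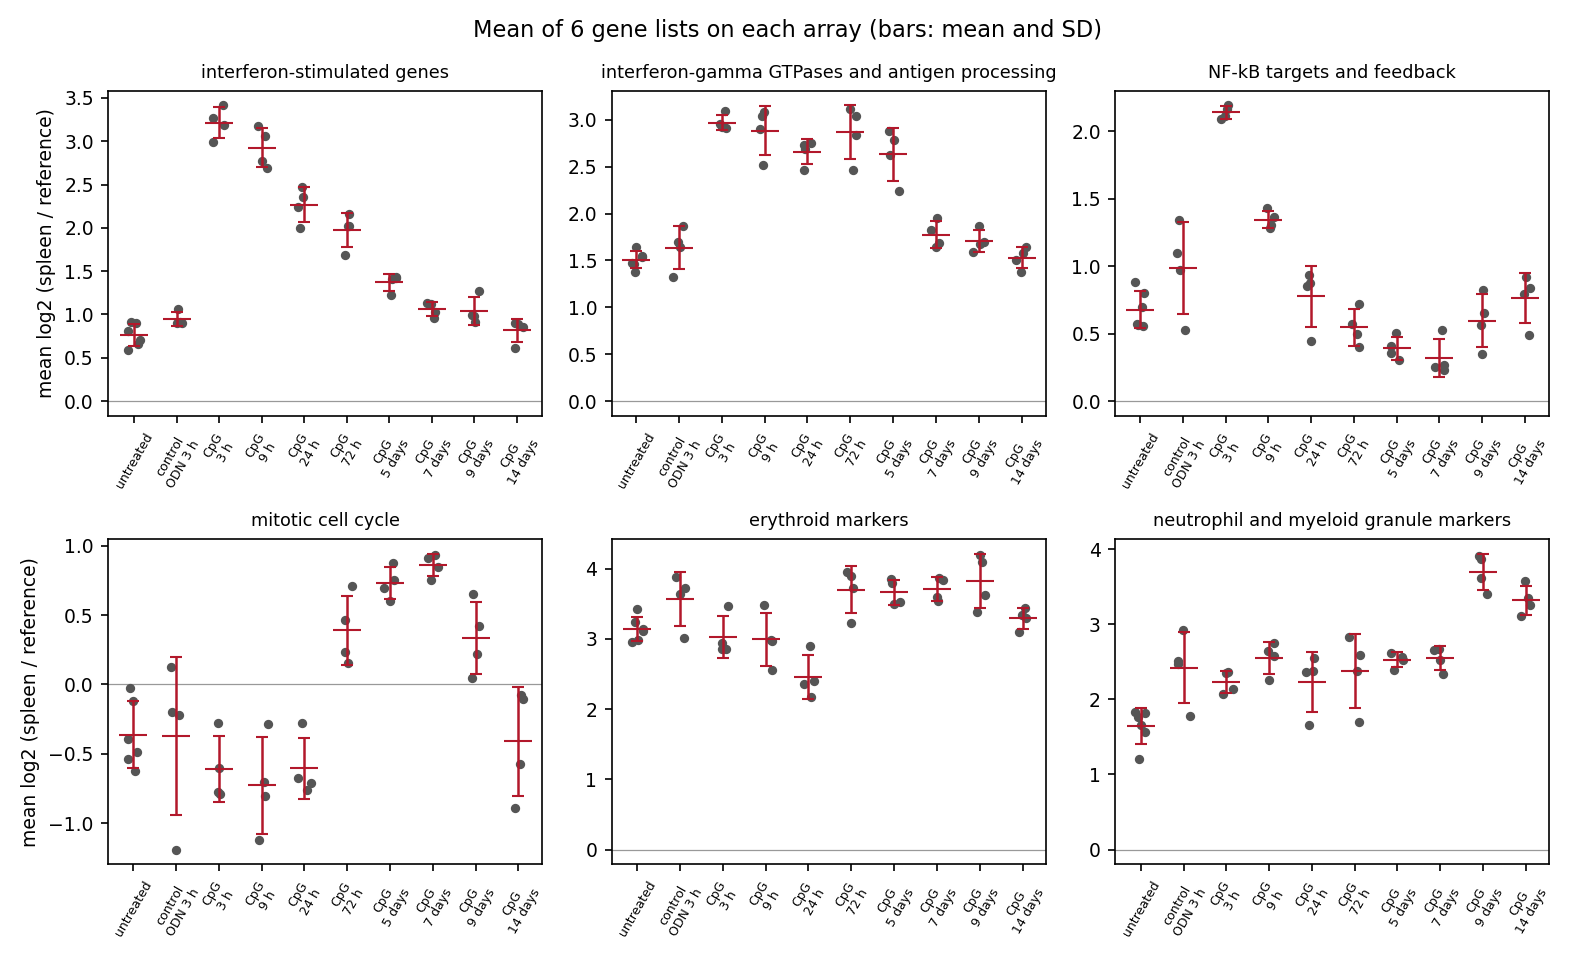
Mean log2 ratio to the reference of 6 gene lists in each group, with dots for single arrays and bars for the group mean and SD (n = 6 untreated, n = 4 otherwise). The interferon-stimulated mean was highest at 3 h (3.21 ± 0.18), the mitotic mean at 7 days (0.86 ± 0.08) and the neutrophil granule mean at 9 days (3.70 ± 0.24).

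After 5 days the highest genes were Apol10a (3.92 ± 0.40), the heavy chain gene Ighg1 (3.67 ± 0.68), Gbp2b (3.01 ± 0.27), the primary granule gene Ctsg (2.90 ± 0.34), Ms4a3, a gene of granulocyte and monocyte progenitors (2.75 ± 0.34), the primary granule gene Prtn3 (2.72 ± 0.30), the ubiquitin-like gene Ubd (2.59 ± 0.44) and Gbp2 (2.49 ± 0.26). The lowest were Vpreb2, a part of the surrogate light chain of B cell precursors (-2.59 ± 0.25), the methyltransferase gene Gnmt (-2.41 ± 0.26), Bbs5 (-2.29 ± 0.32), Krt82 (-2.22 ± 0.28) and Sec14l4 (-2.14 ± 0.23), Ceacam15 (-2.12 ± 0.18), the leukotriene B receptor gene Ltb4r1 (-2.04 ± 0.22) and Krt28 (-1.97 ± 0.17). Their adjusted p did not exceed 9.75e-05.

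Of the DNA replication genes 37 of 38 members rose, 37 adjusted over the list alone (median 0.95, adjusted p = 3.01e-18, adjusted p = 0.0751 with an estimated correlation). They included the origin recognition gene Orc1 (1.87 ± 0.33), Prim2 (1.85 ± 0.29) and Mcm2 (1.59 ± 0.29) and Pole (1.47 ± 0.23). Of the mitotic cell cycle genes 28 of 31 members rose, 30 adjusted over the list alone (median 1.21, adjusted p = 1.08e-15, adjusted p = 0.11 with an estimated correlation), with Top2a (1.76 ± 0.28), Ccnb2 (1.62 ± 0.35) and Ttk (1.60 ± 0.24). DNA repair genes moved with them, and 19 of 29 members rose, 20 adjusted over the list alone (median 0.59, adjusted p = 1.46e-07, adjusted p = 0.0751 with an estimated correlation), with Rad51ap1 (1.64 ± 0.22), Rad54l (1.63 ± 0.24) and Fancd2 (1.49 ± 0.24). Of the interferon-gamma GTPases and antigen processing genes 17 of 21 members rose, 17 adjusted over the list alone (median 1.14, adjusted p = 7.03e-15). Among interferon-stimulated genes 14 of 25 members rose and 1 fell, 14 and 1 adjusted over the list alone (median 0.48, adjusted p = 2.08e-06, adjusted p = 0.11 with an estimated correlation). The neutrophil list, in which 10 of 21 members rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.88, adjusted p = 1.05e-06, adjusted p = 0.328 with an estimated correlation), contained the elastase gene Elane (2.12 ± 0.22).

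Of the T cell markers 2 of 21 members rose and 13 fell, 2 and 14 adjusted over the list alone (median -0.68, adjusted p = 3.72e-08, adjusted p = 0.0972 with an estimated correlation), with Lef1 (-1.61 ± 0.18), Cd3g (-1.54 ± 0.18), Cd28 (-1.44 ± 0.17) and Themis (-1.39 ± 0.29). Of the B cell markers 12 of 21 members fell, 13 adjusted over the list alone (median -0.75, adjusted p = 1.46e-07, adjusted p = 0.0751 with an estimated correlation), with the transcription factor gene Spib (-1.73 ± 0.34), Cd79b (-1.46 ± 0.15) and the IgE receptor gene Fcer2a (-1.09 ± 0.21). Of the megakaryocyte and platelet markers 12 of 15 members rose, 13 adjusted over the list alone (median 0.96, adjusted p = 3.61e-06, adjusted p = 0.0972 with an estimated correlation), with Vwf (1.74 ± 0.31), Rgs18 (1.61 ± 0.30) and Gp1bb (1.42 ± 0.31). Of the erythroid markers 13 of 27 members rose and 1 fell, 14 and 1 adjusted over the list alone (median 0.71, adjusted p = 0.00148, adjusted p = 0.431 with an estimated correlation). The erythroid factor gene Tal1 and the transferrin receptor gene Tfrc rose (1.95 ± 0.33 and 1.71 ± 0.34), whereas Alas2, the erythroid enzyme that starts haem synthesis, fell (-1.48 ± 0.37). NF-kB targets were lower (median -0.34, adjusted p = 0.016, adjusted p = 0.431 with an estimated correlation), with Nfkbia (-1.02 ± 0.19), Zfp36 (-0.90 ± 0.17) and Birc3 (-0.83 ± 0.18) lower and Tnfaip2 higher (1.27 ± 0.18). Of the dendritic cell markers 4 of 19 members rose and 5 fell (4 and 5 adjusted over the list alone), with Clec9a higher (1.40 ± 0.19) and Ccr7 (-1.37 ± 0.28) and Tcf4 (-1.13 ± 0.18) lower, and the list was not called (adjusted p = 0.355).

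In all, 4633 of 15006 genes tested differed, 2624 higher and 2009 lower, with no overlap for 3192 of 13784 genes measured on all their arrays (23.2%, chance 0.952%). Leaving out the arrays with over 1000 missing values gave 2577 genes. The 5 day arrays share no run with untreated arrays, so run and group cannot be told apart.

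At 7 days the top genes were Apol10a (4.31 ± 0.40) and Ighg1 (3.84 ± 0.68). The heavy chain gene annotated as Ighg2c (2.92 ± 0.46), Ms4a3 (2.71 ± 0.34) and Ctsg (2.59 ± 0.34) followed. The lowest were Bbs5 (-1.74 ± 0.32), Igfbp5 (-1.68 ± 0.26), Jhy (-1.60 ± 0.43), Sidt1 (-1.58 ± 0.37) and Vpreb2 (-1.43 ± 0.25). Their largest adjusted p was 0.00909. Of the mitotic cell cycle genes 29 of 31 members rose, 29 adjusted over the list alone (median 1.25, adjusted p = 1.27e-31, 0.0722 with an estimated correlation), with Mki67 (2.10 ± 0.41), Top2a (1.82 ± 0.28), Hmmr (1.80 ± 0.32) and Nuf2 (1.74 ± 0.30). Of the DNA replication genes 30 of 38 members rose, 32 adjusted over the list alone (median 0.91, adjusted p = 1.85e-21, 0.0722 with an estimated correlation), with Orc1 (1.78 ± 0.33), Prim2 (1.44 ± 0.29) and Mcm2 (1.26 ± 0.29). Of the DNA repair genes 13 of 29 members rose, 13 adjusted over the list alone (median 0.34, adjusted p = 1.21e-06, 0.106 with an estimated correlation). In the neutrophil list 12 of 21 members rose and 2 fell, 13 and 2 adjusted over the list alone (median 1.18, adjusted p = 3.65e-12, adjusted p = 0.164 with an estimated correlation), with Chil3 (2.38 ± 0.32) and Ngp (2.33 ± 0.46).

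Of the B cell markers 8 of 21 members fell, 9 adjusted over the list alone (median -0.51, adjusted p = 6.01e-07, adjusted p = 0.0931 with an estimated correlation), with H2-Ob (-1.32 ± 0.28) and Cd79b (-1.28 ± 0.15). Of the T cell markers 1 of 21 members rose and 8 fell, 1 and 10 adjusted over the list alone (median -0.52, adjusted p = 9.65e-07, adjusted p = 0.164 with an estimated correlation), with Cd28 (-1.26 ± 0.17) and Cd3e (-1.04 ± 0.17) lower. NF-kB targets were lower (median -0.45, adjusted p = 0.000433, adjusted p = 0.342 with an estimated correlation), with Nfkbia (-1.20 ± 0.19) and Birc3 (-0.83 ± 0.18). The NK list was lower (median -0.38, adjusted p = 0.0387, adjusted p = 0.606 with an estimated correlation). Erythroid, megakaryocyte and both interferon lists were called higher with adjusted p from 3.33e-06 to 0.00688, and adjusted p from 0.164 to 0.418 with an estimated correlation. Of the 12 lists called at 7 days 0 kept the call with an estimated correlation. In all, 2366 of 15200 genes tested differed, 1319 higher and 1047 lower, with no overlap for 2310 of 14168 genes measured on all their arrays (16.3%, chance 0.952%). Array weights gave 3728. The 7 day arrays share no run with untreated arrays, so run and group cannot be told apart.

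After 9 days neutrophil granule and platelet genes were higher. Highest were Ighg1 (4.83 ± 0.68), the granule genes Ngp (4.52 ± 0.46) and Chil3 (4.40 ± 0.32), Apol10a (4.22 ± 0.40) and Chil4 (3.93 ± 0.23). The lowest included Bbs5 (-1.80 ± 0.32), the granzyme gene Gzma (-1.77 ± 0.29), Cspg5 (-1.74 ± 0.28) and the collagen cross-linking enzyme gene Lox (-1.70 ± 0.37). Adjusted p was at most 0.00191. Of the neutrophil and myeloid granule markers 18 of 21 members rose, 18 adjusted over the list alone (median 2.55, adjusted p = 2.79e-54), with the secondary granule genes Ltf (3.89 ± 0.40) and Camp (3.79 ± 0.33). The list mean was 3.70 ± 0.24 (SD, n = 4) against 1.64 ± 0.24 (SD, n = 6). Of the megakaryocyte and platelet markers 15 of 15 members rose, 15 adjusted over the list alone (median 1.30, adjusted p = 2.55e-18), with Mmrn1 (2.11 ± 0.41), Vwf (1.96 ± 0.31) and Gp6 (1.89 ± 0.27).

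Mitotic, erythroid, DNA replication and interferon-stimulated lists were also called higher and T cell markers lower, with adjusted p from 1.33e-10 to 0.0429 and adjusted p from 0.379 to 0.869 with an estimated correlation. Of the mitotic genes 15 of 31 members rose (24 adjusted over the list alone), with Nusap1 (1.29 ± 0.30) and Tpx2 (1.03 ± 0.24), and of the erythroid markers 14 of 26 members rose (16, and 1 fell, adjusted over the list alone), with Tal1 (1.46 ± 0.33) and Fech (1.28 ± 0.31). In all, 2048 of 15142 genes tested differed, 1272 higher and 776 lower, with no overlap for 1860 of 14045 genes measured on all their arrays (13.2%, chance 0.952%). Without CpG 9 days replicate 4 the count was 1168. No untreated array shares a run with the 9 day arrays, so run and group cannot be told apart.

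The 14 day group asks for long-term changes, and neutrophil granule genes were higher. The highest genes by the naming rule were Ighg1 (3.90 ± 0.68), Lcn2 (3.67 ± 0.32), Ngp (3.53 ± 0.46), Chil4 (3.40 ± 0.23) and Chil3 (3.29 ± 0.32). Ighg1 on the 14 day arrays (2.28 to 5.29) overlapped that after control ODN in the same run. The lowest were the complement receptor gene C3ar1 (-1.78 ± 0.28), Trim66 (-1.64 ± 0.34), Gzma (-1.23 ± 0.29) and Map1b (-1.09 ± 0.16) and Tubb3 (-1.41 ± 0.38), whose call was lost in 5 of 10 leave-one-out fits. The largest adjusted p of these genes was 0.0262. Of the neutrophil and myeloid granule markers 17 of 21 members rose, 19 adjusted over the list alone (median 1.86, adjusted p = 4.3e-53), with Ltf (3.80 ± 0.40) and Lcn2 (3.67 ± 0.32). Of the megakaryocyte and platelet markers 4 of 15 members rose, 12 adjusted over the list alone (median 0.67, adjusted p = 2.78e-07, adjusted p = 0.121 with an estimated correlation). Within the run that holds the 14 day arrays this list was not called for control ODN, 72 h or 7 days against 14 days (median -0.02, -0.16 and -0.04, adjusted p = 0.791, 0.51 and 0.659). Of the NK and cytotoxic markers 4 of 17 members fell, 4 adjusted over the list alone (median -0.27, adjusted p = 0.00482, adjusted p = 0.907 with an estimated correlation), with the transcription factor gene Tbx21 (-0.70 ± 0.16). Of the ribosomal proteins 2 of 48 members fell, 2 adjusted over the list alone (median -0.09, adjusted p = 0.0365, adjusted p = 0.907 with an estimated correlation).

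Pancreas acinar markers, digestive enzymes of the exocrine pancreas, were lower as a list (median -3.33, adjusted p = 2.44e-05, adjusted p = 0.907 with an estimated correlation), although 0 of 15 members passed limma's test and 7 had an unadjusted p below 0.05. Their mean was 0.72 ± 0.34 (SD, n = 4) at 14 days and 3.52 ± 1.93 (SD, n = 6) in untreated spleens. The interferon-stimulated list, at 0.82 ± 0.14, was not called (adjusted p = 0.735), nor was the mitotic list (adjusted p = 0.562). In all, 681 of 15003 genes tested differed, 415 higher and 266 lower, with no overlap for 1070 of 14030 genes measured on all their arrays (7.63%, chance 0.952%). The count was 313 without untreated replicate 1, 425 without untreated replicate 2, and 202, 291 and 380 without 14 day replicates 2, 3 and 4. No untreated array shares a run with the 14 day arrays, so run and group cannot be told apart, and leaving out arrays with over 1000 missing values gave 82 genes. Array weights gave 1148, single features 1125 and quantile scaling 353.

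Direct tests between times compared 4 arrays with 4. From 24 h to 72 h the erythroid markers rose (18 of 27 higher, median 1.24, adjusted p = 6.49e-31). So did the mitotic genes (20 of 31 higher, median 0.90, adjusted p = 3.14e-27). Between 5 and 9 days the neutrophil granule genes rose (15 of 21 higher, median 0.92, adjusted p = 5.37e-15). The interferon-gamma GTPases fell (13 of 21 lower, median -0.89, adjusted p = 1.42e-14). DNA replication genes fell between the same times (26 of 38 lower, median -0.71, adjusted p = 9.48e-15). From 9 to 14 days mitotic genes fell (13 of 31 lower, median -0.72, adjusted p = 3.12e-13). Neutrophil genes were lower as a list (5 of 21 lower, median -0.56, adjusted p = 0.0133). These tests used the preset correlation alone. The 24 h and 72 h arrays share no run, nor do the 9 and 14 day arrays. Days 5 and 9 share 1 with 1 and 2 arrays, so run and time cannot be told apart.

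Within the run that holds the 72 h, 7 day and 14 day arrays, 72 h differed from 14 days in 3838 genes and 7 days from 14 days in 2651. There the interferon-stimulated genes were higher at 72 h (19 of 25 higher, median 1.28, adjusted p = 4.44e-22). So were the interferon-gamma GTPases (16 of 21 higher, median 1.19, adjusted p = 5.86e-15). Mitotic genes were higher at 7 days (29 of 31 higher, median 1.29, adjusted p = 4.95e-23). So were the DNA replication genes (31 of 38 higher, median 0.98, adjusted p = 3.64e-21). B cell markers were lower at 7 days (12 of 21 lower, median -0.72, adjusted p = 7.49e-09). List tests within runs used the preset correlation alone. In the run that holds 3 h, 9 h and 24 h arrays, interferon-stimulated genes were lower at 24 h than at 3 h (5 of 25 lower, median -1.01, adjusted p = 6.33e-22), and NF-kB targets too (7 of 21 lower, median -1.19, adjusted p = 1.45e-33), with 3 arrays against 2. Over the 8 CpG times together limma's F test called 9250 of 14557 genes (63.5%).

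A panel of 18 measured genes was followed whatever its result, and its log2 differences from untreated are given in the order 3 h, 9 h, 24 h, 72 h, 5, 7, 9 and 14 days. A number in brackets after a time counts the leave-one-out fits, of 10, that lost the call. Il12b stood at 3.67, 2.82, 1.11, -0.18, 0.34, 0.18, 0.99 and -0.18 (SE 0.18 to 0.23), called at 3 h, 9 h, 24 h and 9 days. It had too few values for a test at 72 h and 14 days. Il6 stood at 3.30, 1.72, 1.08, 0.06, 0.05, -0.37, -0.37 and -0.11 (SE 0.29), called at 3 h and 9 h and, with losses, at 24 h (1). Tnf stood at 2.25, 1.16, 0.34, 0.08, -0.16, -0.27, -0.19 and 0.30 (SE 0.22), called at 3 h and 9 h. Il10 stood at 1.64, 1.83, 1.27, 0.89, 0.43, 0.18, -0.28 and 0.03 (SE 0.20), called at 3 h, 9 h, 24 h and 72 h. For the chemokines, Cxcl10 stood at 4.46, 2.92, 1.72, 1.68, 0.92, -0.34, -0.31 and -0.28 (SE 0.30), called at 3 h, 9 h, 24 h and 72 h and, with losses, at 5 days (2). Ccl2 stood at 1.16, 0.80, 0.00, -0.74, -0.72, -0.36, -0.62 and -0.14 (SE 0.25), called at 3 h and, with losses, at 9 h (6), 72 h (7) and 5 days (4). Ifit3 stood at 4.44, 4.06, 2.89, 1.58, 0.26, -0.55, -0.59 and -0.67 (SE 0.28), called at 3 h, 9 h, 24 h and 72 h. The interferon regulatory factor gene Irf7 stood at 0.79, 1.15, 1.03, 0.67, 0.33, 0.21, 0.62 and 0.47 (SE 0.23), called at 9 h and 24 h and, with losses, at 3 h (2) and 72 h (6).

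Of the receptor and its signalling partners, Tlr9 stood at 0.77, 0.68, 0.17, 0.20, 0.50, 0.03, 0.70 and 0.43 (SE 0.20), called at 3 h and, with losses, at 9 h (4), 5 days (7) and 9 days (2). Myd88, the adaptor, stood at 1.42, 1.08, 0.86, 0.57, 0.45, -0.31, -0.11 and 0.20 (SE 0.19), called at 3 h, 9 h and 24 h and, with losses, at 72 h (7). Unc93b1, its chaperone, stood at 0.52, 0.27, -0.08, -0.26, -0.67, -0.26, -0.09 and 0.35 (SE 0.36), called at no time. Of the feedback inhibitors, Nfkbia stood at 1.38, 0.52, -0.65, -0.93, -1.02, -1.20, -0.23 and -0.37 (SE 0.19), called at 3 h, 72 h, 5 days and 7 days and, with losses, at 24 h (3). Socs3 stood at 3.32, 2.14, 1.17, 0.73, 0.54, -0.21, -0.14 and 0.20 (SE 0.27 to 0.34), called at 3 h, 9 h and 24 h. It had too few values for a test at 14 days. The cytokine gene Ifng stood at 0.05, 0.35, 0.08, 0.18, 0.32, -0.10, 0.65 and 0.37 (SE 0.19), called at 9 days (1). For dividing cells, Mki67 stood at -0.59, -0.51, -1.49, 0.86, 1.00, 2.10, 1.06 and -0.11 (SE 0.41), called at 7 days and, with losses, at 24 h (1). The sliding clamp gene Pcna stood at -0.21, -0.37, 0.25, 0.71, 1.06, 1.00, 0.33 and -0.03 (SE 0.21), called at 5 days and 7 days and, with losses, at 72 h (4). The T cell gene Cd3e stood at -0.07, -0.46, -0.48, -0.95, -1.24, -1.04, -0.59 and -0.13 (SE 0.17), called at 72 h, 5 days and 7 days and, with losses, at 9 days (1). The neutrophil elastase gene Elane stood at 0.01, 0.17, 0.56, 1.01, 2.12, 2.05, 2.80 and 1.86 (SE 0.22 to 0.24), called at 72 h and at each later time.

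**Figure D3:**
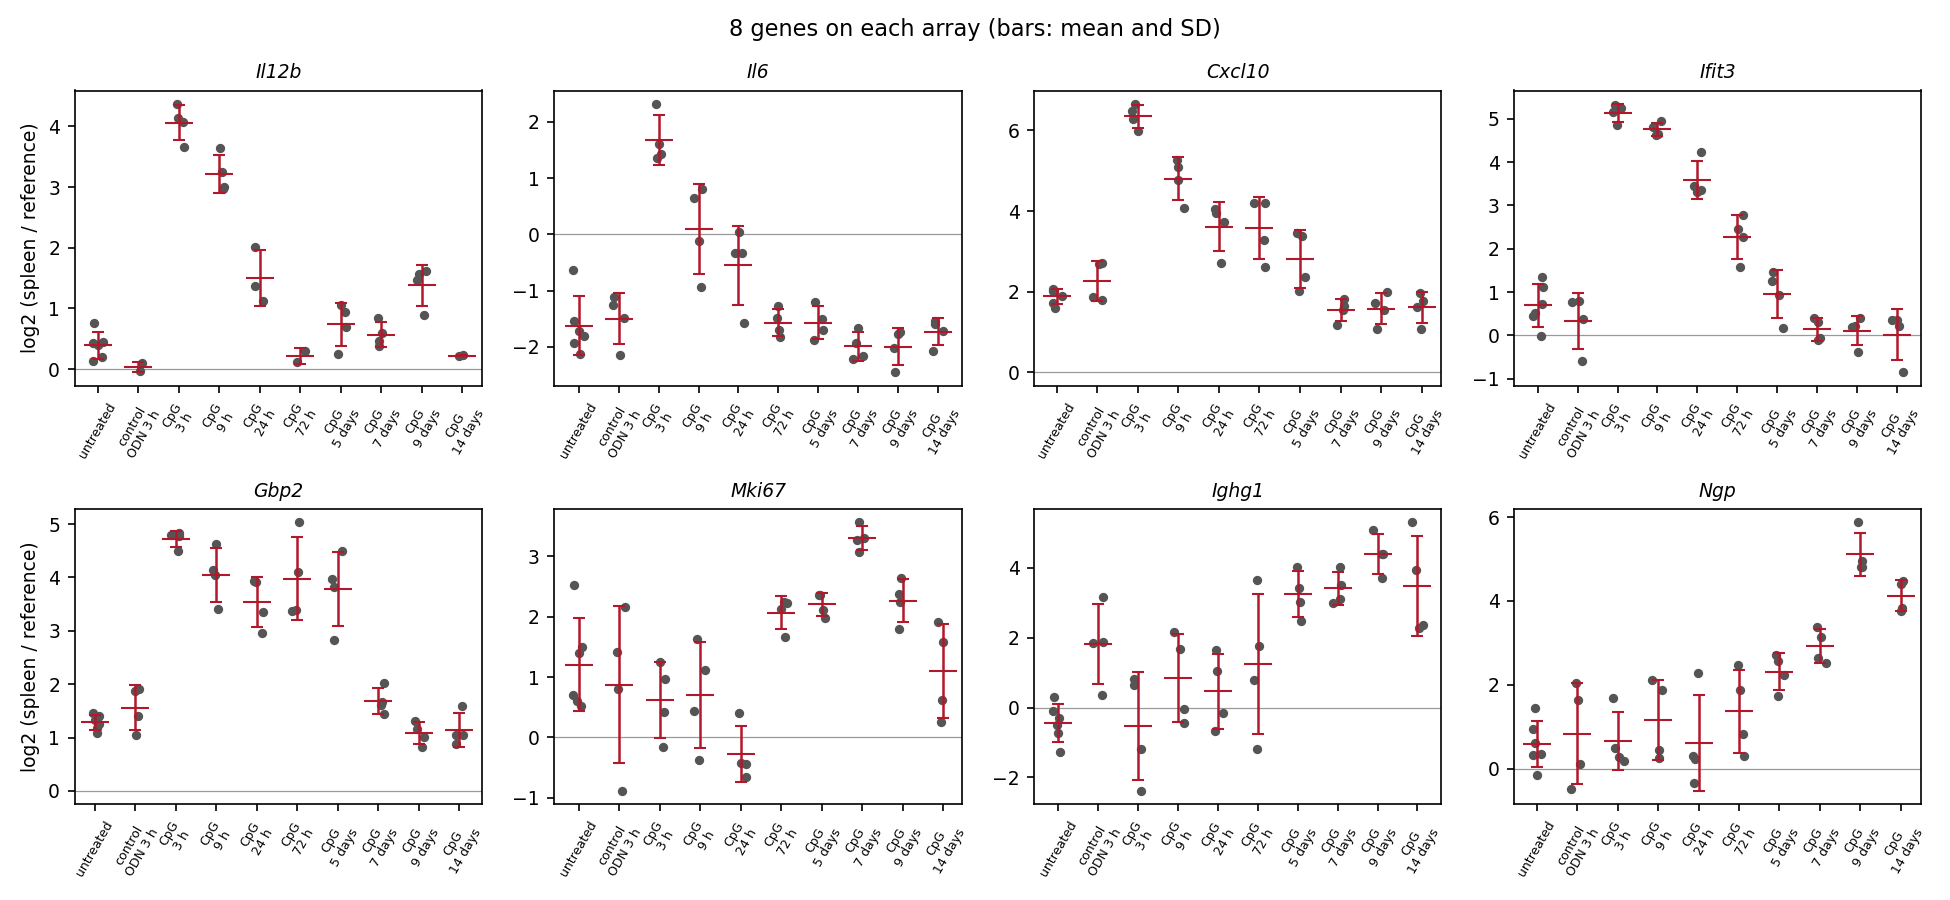
Log2 ratio to the reference of 8 genes in each group, with dots for single arrays and bars for the group mean and SD (n = 6 untreated, n = 4 otherwise, fewer where a value is missing). Il12b, Il6 and Cxcl10 were highest at 3 h, Mki67 at 7 days, and Ighg1 and Ngp at 9 days.

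Control ODN at 3 h against untreated gives the background of injecting oligodeoxynucleotides that are not the CpG ODN. Its highest genes were Slfn4 (1.57 ± 0.31) and Mmp8 (1.56 ± 0.38), the glucocorticoid-induced gene Fkbp5 (1.48 ± 0.34), the decoy IL-1 receptor gene Il1r2 (1.43 ± 0.27) and the clotting factor gene F13a1 (1.40 ± 0.26). The lowest were Zfp142 (-1.25 ± 0.27), Krt34 (-0.94 ± 0.22), Rdh18-ps (-0.91 ± 0.20), Vpreb2 (-0.90 ± 0.25) and Crtac1 (-0.90 ± 0.20). Their adjusted p did not exceed 0.0387, and these calls were lost in 2 to 7 of 10 leave-one-out fits. Of the interferon-stimulated genes 0 of 25 passed limma's test, 5 had an unadjusted p below 0.05, and the list was not called (median log2 difference 0.22, adjusted p = 0.225). Of the panel followed whatever its result, Myd88 and Socs3 (0.92 ± 0.27, call lost in 8 of 10 fits) were called. Il12b had too few values, and the others, from -0.64 (Ccl2) to 0.60 (Elane), were not called, with Il6 and Cxcl10 at 0.13 ± 0.29 and 0.38 ± 0.30.

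Of the neutrophil and myeloid granule markers 4 of 21 members rose, 14 adjusted over the list alone (median 0.62, adjusted p = 3.02e-08, adjusted p = 0.273 with an estimated correlation), with the neutrophil chemokine receptor gene Cxcr2 at 1.09 ± 0.18, a call lost in 1 of 10 fits. Of the megakaryocyte and platelet markers 5 of 15 members rose, 9 adjusted over the list alone (median 0.74, adjusted p = 6.35e-06, adjusted p = 0.273 with an estimated correlation). Lists for the Toll-like receptor pathway, erythroid cells, monocytes and macrophages, NF-kB targets and dendritic cells were called higher with adjusted p from 0.00889 to 0.0142, and adjusted p from 0.563 to 0.75 with an estimated correlation. Of the 19 dendritic cell markers 0 passed limma's test (3 adjusted over the list alone, 6 at an unadjusted p below 0.05). Myd88 stood at 1.01 ± 0.19 (call lost in 2 of 10 fits) and Cd14 at 1.09 ± 0.25 (call lost in 3 of 10 fits).

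In all, 531 of 15084 genes tested differed, 369 higher and 162 lower, and 3461 genes had an unadjusted p below 0.05, with no overlap for 526 of 13968 genes measured on all their arrays (3.77%, chance 0.952%). This count depended on single arrays. Without untreated replicates 1, 2, 5 or 6 it was 188, 155, 137 or 91, and without control ODN replicates 2, 3 or 4 it was 163, 4 or 2321. Without control ODN replicate 1 limma called 0 genes, with 2370 at an unadjusted p below 0.05. With the replicate block it was 28, without arrays with over 1000 missing values 105, and with quantile scaling 184 (109 higher and 75 lower, 59.2% higher against 69.5%). Array weights gave 1097 and single features 947. All control ODN arrays lie in a run without untreated arrays, so run and group cannot be told apart. Within that run they differed from the 14 day arrays in 578 genes.

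CpG ODN against control ODN at 3 h compares both mixtures at the same dose and time. The CpG group was higher in Ifit3 (4.79 ± 0.30), Ccl12 (4.65 ± 0.34), Impg2 (4.23 ± 0.24) and Ccl4 (4.16 ± 0.23), Ifit2 (4.12 ± 0.23), Cxcl10 (4.08 ± 0.32), Ifi204 (3.95 ± 0.23) and Phf11d (3.89 ± 0.21). It was lower in Tcf21 (-3.21 ± 0.26), Slc40a1 (-3.08 ± 0.23), Id4 (-2.90 ± 0.34) and Arvcf (-2.53 ± 0.25), Gpd1 (-2.51 ± 0.26), Hpgd (-2.47 ± 0.28) and Pcdh18 (-2.21 ± 0.43) and Tlx1, a transcription factor gene needed for spleen development (-2.23 ± 0.37). None of their adjusted p values exceeded 0.000241. Of the interferon-stimulated genes 23 of 25 members rose, 23 adjusted over the list alone (median 2.17, adjusted p = 1.14e-85). Of the NF-kB targets 14 of 22 members rose, 15 adjusted over the list alone (median 0.90, adjusted p = 3.08e-19), with Nfkbiz (3.42 ± 0.17) and Gadd45b (2.77 ± 0.24). Of the interferon-gamma GTPases and antigen processing genes 16 of 20 members rose, 18, and 1 fell, adjusted over the list alone (median 1.19, adjusted p = 5.31e-18). Of the cytokines 10 of 22 members rose, 12 adjusted over the list alone (median 0.54, adjusted p = 1.29e-09), with Il6 (3.18 ± 0.31) and Tnf (2.02 ± 0.24). Of the chemokines 12 of 25 members rose and 2 fell, 13 and 3 adjusted over the list alone (median 0.54, adjusted p = 4.71e-13). Of the macrophage activation effectors 10 of 21 members rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.47, adjusted p = 9.45e-12), with Mmp13 (3.15 ± 0.21) and Acod1 (2.94 ± 0.25).

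SOCS and DUSP feedback was called higher, and B cell and erythroid markers lower, with adjusted p from 0.00395 to 0.00989 and adjusted p from 0.291 to 0.697 with an estimated correlation. Of the B cell markers 1 of 21 members rose and 7 fell (1 and 7 adjusted over the list alone), with Cd79b (-1.13 ± 0.16) and Cd37 (-0.78 ± 0.19), and of the erythroid markers 1 of 27 members rose and 5 fell (1 and 6 adjusted over the list alone). Of the panel Nfkbia (1.70 ± 0.21), Ccl2 (1.80 ± 0.28) and Socs3 (2.41 ± 0.29) were also higher, as was Il10. There Il12b had too few values, and the genes not called ranged from -0.59 (Elane) to 0.49 (Irf7). The mixtures were not told apart by the test in Myd88, with a 95% interval of the difference of -0.01 to 0.84, in Tlr9 (-0.19 to 0.69), in Irf7 (-0.01 to 1.00) or in Pcna (-0.84 to 0.09). For dendritic cell markers the median was -0.25 and the test's direction upward, without a call (adjusted p = 0.911). In all, 3124 of 15068 genes tested differed, 1391 higher and 1733 lower, with no overlap for 2874 of 14328 genes measured on all their arrays (20.1%, chance 2.86%). Without control ODN replicate 3 the count was 1916, and the groups share no run.

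Of the 1774 genes called at 3 h after CpG ODN, 84 were called in the same direction after control ODN and 15 in the opposite one, where independent lists would share 34.8. Both comparisons share the untreated arrays. With these split between the comparisons the mean count over 10 splits was 22.9, from 0 to 60, against 12.5 for independent lists. At later CpG times 1200 of the 1774 genes were called again in the same direction, where independent lists would share 489, and 2 were called at all 7 later times. With the untreated arrays split the count called again at any later time had a mean of 674 (633 to 712), against 238 for independent lists. From 9 h to 14 days, in order of time, the mean counts shared with the split arrays were 514, 330, 238, 261, 87.9, 73.5 and 11.3, and those for independent lists 42.1, 53.3, 47.9, 149, 62.9, 53 and 15. Without the split, 0, 39, 45, 169, 135, 96 and 33 were opposite calls. At 7 days 86 higher and 147 lower calls were shared (102 and 41.3 for independent lists).

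CpG 5 days against 72 h follows the late change without the untreated arrays. The lowest genes were Klrc1, which encodes the NK receptor NKG2A (-2.34 ± 0.62), Stfa3 (-2.13 ± 0.39) and Gzma (-1.88 ± 0.31), Csta2 (-1.72 ± 0.42) and Gnmt (-1.65 ± 0.29). The highest were the pyruvate kinase gene Pklr (1.51 ± 0.24), the histone genes H3c2 (1.39 ± 0.32) and H2bc15 (1.35 ± 0.36), Rgs18 (1.34 ± 0.33) and Cyp2e1 (1.33 ± 0.31). The calls of Klrc1, Csta2, H3c2, H2bc15 and Rgs18 were lost in 4 of 8, 4 of 8, 2 of 8, 3 of 8 and 3 of 8 leave-one-out fits, and that of Cyp2e1 without CpG 72 h replicate 3 (1.06, adjusted p = 0.0709). Adjusted p was at most 0.0301.

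Among interferon-stimulated genes 9 of 25 members fell, 15 adjusted over the list alone (median -0.52, adjusted p = 2.73e-15), with Trim30a (-1.40 ± 0.23), Ifit1 (-1.21 ± 0.19) and Oas2 (-1.02 ± 0.15). Of the NK and cytotoxic markers 4 of 16 members fell, 9 adjusted over the list alone (median -0.61, adjusted p = 4.9e-11), with Gzmb (-2.26 ± 0.35) and Klre1 (-1.18 ± 0.22). Of the monocyte and macrophage markers 5 of 23 members fell, 11 adjusted over the list alone (median -0.47, adjusted p = 3.82e-08), with Ly6c1 (-1.17 ± 0.23) and Hmox1 (-0.91 ± 0.20). Of the complement genes 2 of 15 members fell, 7 adjusted over the list alone (median -0.54, adjusted p = 4.03e-05), with Cfb (-1.52 ± 0.24). Of the plasma cell markers 2 of 19 members fell, 3 adjusted over the list alone (median -0.37, adjusted p = 0.000167). Across arrays within groups this list's mean moved with that of the pancreas acinar markers, which stood at 1.78 ± 2.48 (SD, n = 4) at 5 days and 2.33 ± 1.72 (SD, n = 4) at 72 h. Of the macrophage activation effectors 1 of 21 members fell, 1 adjusted over the list alone (median -0.21, adjusted p = 0.00851). DNA replication, mitotic, DNA repair, megakaryocyte and neutrophil lists were called higher, and chemokine, B cell, cytokine and T cell lists lower, with adjusted p from 2.44e-09 to 0.0493 and adjusted p from 0.0757 to 0.868 with an estimated correlation. Elane rose (1.10 ± 0.24), and so did the dendritic cell genes Itgae (1.12 ± 0.19) and Clec9a (0.99 ± 0.21). Of the panel Ifit3 fell (-1.32 ± 0.30, call lost in 2 of 8 fits). Again Il12b had too few values, and the genes not called ranged from -0.76 (Cxcl10) to 0.35 (Pcna).

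In all, 510 of 14926 genes tested differed, 185 higher and 325 lower, with no overlap for 1409 of 13941 genes measured on all their arrays (10.1%, chance 2.86%). The count was 279 and 260 without 72 h replicates 1 and 3, and 253, 266 and 230 without 5 day replicates 1, 2 and 4. A fit of these 8 arrays alone called 28 genes, leaving out arrays with over 1000 missing values gave 79, array weights gave 1651, and the groups share no run.

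Stromal and fat markers were called as lists in none of the 11 comparisons. The lowest adjusted p of the endothelial and fibroblast markers was 0.0742 at CpG 72 h against untreated (median -0.18) and that of the adipocyte markers 0.115 at CpG 9 h against untreated (median -0.10). Single members moved: the proteoglycan gene Dcn fell at 5, 7 and 14 days (-1.32 ± 0.27, -1.15 ± 0.27 and -1.30 ± 0.27), and the glucose transporter gene Slc2a4 rose at 5, 7 and 9 days (1.34 ± 0.44, 1.71 ± 0.40 and 1.81 ± 0.40). Over all 275 pairs of list and comparison 115 were called, 33 of them also with an estimated correlation. The median, mean and test differed in sign for 22 pairs, of which 0 were called by camera.

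Transcripts of pancreas acinar enzymes differed widely between spleens of the same group. Their list mean ran from 0.48 to 5.67 among untreated arrays (mean 3.52 ± 1.93, SD, n = 6) and was 2.70 ± 2.91 at 3 h (SD, n = 4). Among 24 other lists the plasma cell mean followed the acinar mean most closely across the 42 arrays, each taken as deviation from its group (Pearson's r 0.57, permutation p = 0.00057, 0.0137 adjusted, Spearman's rho 0.507, permutation p = 0.00273, 0.0655 adjusted). Without the 2 arrays farthest from the acinar median r was 0.549, and the permutations, within groups and two-sided, numbered 100000.

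**Figure D4:**
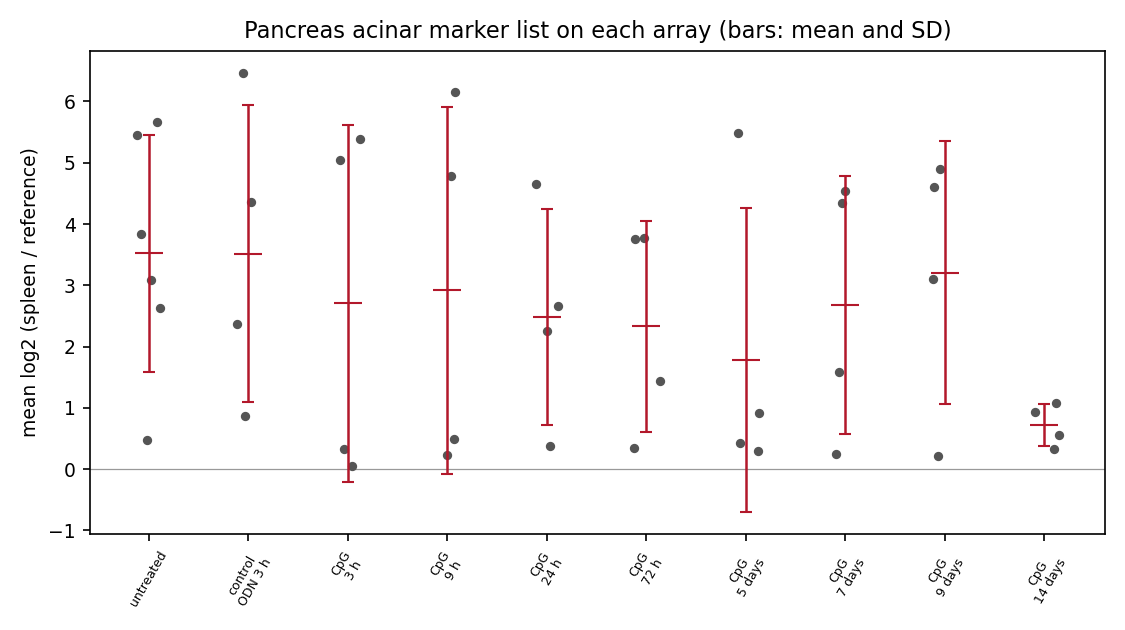
Mean log2 ratio to the reference of the pancreas acinar markers on each array, by group, with bars for the group mean and SD. Untreated arrays run from 0.48 to 5.67 and the 14 day arrays from 0.34 to 1.08.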

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

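The tests of acinar genes moving together, of single control ODN arrays, of held-out arrays, of calls shared with CpG ODN and of granule timing between 5 and 9 days and between 7 and 14 days were chosen after the result was seen. Genes of the Reg family were chosen after their values were seen.

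Acinar enzyme transcripts were high on some arrays and near the array median on others of the same group, with a mean of 5.48 on CpG 5 days replicate 3, far from the other 3 arrays (0.29 to 0.91). A general fault of these arrays is argued against by the means of 24 other lists, whose median absolute correlation with the acinar mean was 0.125, while pancreas tissue taken with some spleens may be the source, as the 10 acinar genes moved together (median pairwise r 0.941, lowest 0.826). For Reg3a and Reg2, made in the pancreas and gut among other tissues and called higher at 9 h and 24 h, a larger share of pancreas tissue at those times as the whole cause is argued against: with the acinar mean as covariate 4 of 4 gene and time pairs were still called. Reg3a went from 3.36 ± 0.96 to 3.67 ± 0.68 at 9 h and from 3.76 ± 0.96 to 4.29 ± 0.69 at 24 h, and Reg2, with 3 treated and 5 untreated values, from 4.56 ± 1.45 to 4.27 ± 0.76 and from 4.75 ± 1.45 to 4.97 ± 0.75. At 9 h Reg2 ran from 0.04 to 9.73 and the acinar gene Amy2 from -0.17 to 9.78. Standard errors fell with the covariate, so Reg values partly followed the acinar genes. No biological explanation was tested for the acinar genes, since their values varied within groups, and a response of Reg genes in pancreas tissue of the sample, or in the spleen, stays open as untested.

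Genes called after control ODN may rest on single arrays: without control ODN replicate 1 limma called 0 genes, with 2370 at an unadjusted p below 0.05. A shift between runs cannot be told apart from a response, because no untreated array shares the run. The called genes kept a median difference of 0.453 from the CpG 14 days arrays of that run against 0.71 from untreated, 96% in the same direction, but the bound set for this test was wrong, because genes chosen with the same arrays keep their chance part. On held-out arrays (500 genes, 6 pairs) the mean was 0.194 within the run (0.0545 to 0.357) and 0.439 against untreated (0.284 to 0.635). A response that CpG ODN also gives cannot be told apart either, with 22.9 shared calls (0 to 60) against 12.5 for independent lists.

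Granule genes of successive neutrophil stages differed in timing. The mean of 7 secondary and tertiary granule genes minus that of 5 early genes (primary granule genes and Ms4a3) was -0.21 ± 0.24 in untreated spleens (SD, n = 6) and 0.72 ± 0.40, 0.73 ± 0.59, -0.37 ± 0.39, -1.15 ± 0.26, -1.69 ± 0.24, -1.23 ± 0.12, 0.04 ± 0.19 and 0.76 ± 0.19 at the 8 CpG times in order (SD, n = 4). A shift between runs as the whole cause is argued against between 7 and 14 days, whose arrays share 1 run and did not overlap (difference 1.99), but cannot be told apart between 5 and 9 days, because the run that holds both times has a single 5 day array (difference 1.67 there), so the bound set for this test was wrong. Granulocyte precursors that mature between 5 and 9 days are a candidate explanation, which the difference between these times (1.74) cannot decide, since the score was formed after the timing was seen. An inflow of mature cells was not tested.

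For each of the 8 CpG times against untreated, 1 of 100 splits of the same arrays, the real one, called as many genes. This argues against a chance division of the arrays as the source of these counts. It cannot tell treatment from a shift between runs, since the runs largely follow the real groups. The highest other splits called 712, 529, 1197, 1469, 2199, 725, 383 and 222 genes, in order of time, against 1774, 1289, 1656, 2267, 4633, 2366, 2048 and 681. CpG against control ODN at 3 h and 5 days against 72 h had 1 of 35 splits, with 958 and 171 as the highest others against 3124 and 510. For control ODN 3 of 100 splits called as many as the real one (531). Parting control ODN replicates 1, 2 and 3 with untreated replicate 4 from the rest called 1308, which points to such a structure. The count also depends on single arrays.

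An array lay far from the others of its group in 29 of 454 tested groups (6.39%) over 46 measures, where chance gives about 1 in 20. Untreated replicate 5 had 1740 missing values. The median correlation with the group was 0.893 for CpG 72 h replicate 3 and 0.957 for 7 days replicate 3. For interferon-stimulated genes the means were 1.23 on 5 days replicate 4, 0.61 on 14 days replicate 2 and 1.07 on control ODN replicate 1. Cytokines stood at 0.62 on 14 days replicate 2, and NF-kB targets at 0.44 on 24 h replicate 4 and 0.53 on 7 days replicate 3. Macrophage effectors stood at -0.24 on 5 days replicate 4, and DNA repair at 0.00806 on 9 days replicate 3 and -0.40 on control ODN replicate 1. Marker means were 2.17 for B cells on 72 h replicate 4, -0.0185 for plasma cells on 3 h replicate 3 and 3.47 for erythroid cells on 3 h replicate 1. They were 0.0802 for endothelial cells on 9 h replicate 2, and 0.73 and 1.04 for adipocytes on untreated replicate 6 and 72 h replicate 4.

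Among single genes, Myd88 stood at 1.08 on 9 h replicate 4 and 0.41 on 14 days replicate 1, Nfkbia at -0.40 on 24 h replicate 4 and Ifng at 2.76 on 9 days replicate 4. Socs3 stood at -2.11 on 72 h replicate 4, Ifit3 at 4.24 on 24 h replicate 1 and -0.85 on 14 days replicate 2, and Pcna at -0.57 on control ODN replicate 1. Cd3e stood at 0.90 on 9 h replicate 1 and Elane at 4.30 on 9 days replicate 1.

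Some lists were called higher at 1 time and lower at another, and direct tests with the preset correlation give the size of the difference, whose call the choice of these lists largely set. The median log2 difference was -1.56 for NF-kB targets at 7 days against 3 h (adjusted p = 5.61e-33), 1.75 for mitotic genes at 7 days against 9 h (adjusted p = 2.06e-28) and 1.29 for DNA replication at 5 days against 9 h (adjusted p = 3.48e-21). It was -1.08 for NK markers at 7 days against 72 h (adjusted p = 9.09e-16), 1.24 for erythroid markers at 72 h against 24 h (adjusted p = 6.49e-31) and -0.20 for ribosomal proteins at 14 days against 24 h (adjusted p = 0.00141). Among features without a gene symbol, 345 of 6916 were called at 3 h after CpG ODN (230 higher) and 129 of 6749 after control ODN.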

How the results depend on the processing

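The acinar covariate, the limit of 1000 missing values and the fixed run block were chosen after the result was seen. The number of arrays limits these results. All 11 counts stayed within 1.5 times under subtracted medians, genes on all arrays only, at least 2 values per group, robust spread and the acinar covariate. Under the settings named next, 0 of 980 differences of named genes reversed where the main or the altered fit called the gene. Signs of differences called in neither fit were not compared. Calls changed under subtracted medians (8 lost), quantile scaling (79 lost, 4 gained), the replicate block (105 lost) and the acinar covariate (22 lost, 1 gained). At the lowest and highest value with 1 array left out 141 and 112 were lost, and 4 and 9 gained. Of 855 calls 262 were lost in at least 1 leave-one-out fit. Among 270 with several features 107 lost the call and 5 reversed on the feature with the smallest difference: Sptb at 3 h (-0.26) and 9 h (-0.16), Klrk1 at 9 h (-0.10), Itgae at 9 h (0.40) and Rfc5 for CpG against control ODN (-0.13), and the cause was not tested.

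In the order of the 8 CpG times, control ODN, CpG against control ODN and 5 days against 72 h, an adjusted p below 0.01 gave 1178, 742, 795, 873, 2824, 1178, 909, 143, 26, 1636 and 104 genes, and a log2 difference of at least 1 gave 540, 392, 333, 315, 764, 419, 387, 87, 71, 734 and 126, which follows from the stricter rules. Array weights gave 2678 for 3 h, 5639 for 72 h, 3728 for 7 days, 1148 for 14 days, 1097 for control ODN and 1651 for 5 days against 72 h. Fitting the arrays of both groups alone gave 1070 for 24 h, 2004 for CpG against control ODN and 28 for 5 days against 72 h and 0 for control ODN (limma, with 3175 at an unadjusted p below 0.05), with fewer arrays to estimate the spread. For 14 days and control ODN quantile scaling gave 353 and 184, single features 1125 and 947, and runs as a random block 449 and 134. The replicate block gave 28 for control ODN. Without arrays with over 1000 missing values the counts were 878 for 72 h, 2577 for 5 days, 82 for 14 days, 105 for control ODN and 79 for 5 days against 72 h, from fewer arrays. Runs as a fixed block on genes measured on all arrays, with 1 untreated array, gave 392 for 3 h, 142 for 9 h and 133 for 24 h, where these genes without the block gave 1601, 1151 and 1540. Except where named, the cause was not tested.

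Leaving out 1 array in turn gave, in the order above, 1430 to 1715, 960 to 1272, 832 to 2572, 1126 to 2929, 3735 to 4459, 1617 to 2301, 1168 to 2135, 202 to 762, 0 to 2321, 1916 to 3793 and 230 to 532. Of 115 list calls 33 held with camera at an estimated correlation on genes measured on all arrays, a filter that alone lost 13 and gained 3, and the cause of the other losses was not tested. Of 275 list tests fry lost 22 calls and gained 22, quantile scaling 15 and 12, and 0 reversed. The 1200 genes called at 3 h and later were 688 at an adjusted p below 0.01, by its stricter rule. With the untreated arrays split the mean was 673.8, from fewer arrays. Replicate numbers were not taken to pair the samples: over 180 pairs of arrays with the same number r ran from -0.373 to 0.52, with 63 over 0.1 and a median of 0.0261 against -0.0158 for 612 other pairs. Of 42 arrays 20 correlated best with 1 of their own number, a hint from the data alone.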

Other observations

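All families and tests here were chosen after the result was seen. They are 7 gene families, found by looking through 516 families of symbols and by hand, in 11 comparisons, adjusted over these 77 tests alone. The run limits of each comparison hold here too. Of 36 calls with the preset correlation 0 changed the sign of the median under subtracted array medians or quantile scaling, which shifted the median of all genes by at most 0.0125. Eosinophil granule proteins, the toxic proteins of eosinophils, rose at 14 days (6 of 6 higher, median 1.63, adjusted p = 4.89e-14, 0.0173 with an estimated correlation), with Epx (3.20 ± 0.41) and Prg2 (2.26 ± 0.44). Immunoglobulin heavy constant genes rose at 9 days (3 of 6 higher, median 0.92, adjusted p = 0.000224, 0.00598 with an estimated correlation). They included Ighg1 (4.83 ± 0.68), Ighg2c as annotated (3.84 ± 0.46) and Igha (1.86 ± 0.27). The family was higher at 14 days (2 of 6 higher, median 1.02, adjusted p = 0.00338, 0.0299 with an estimated correlation). After control ODN, in the same run, its median was 0.54 (adjusted p = 0.307). Klra genes, which encode Ly49 receptors of NK cells, rose at 72 h (10 of 12 higher, median 0.94, adjusted p = 4.19e-09, 0.0353 with an estimated correlation) and fell from 72 h to 5 days (8 of 12 lower, median -1.15, adjusted p = 1.04e-17, 0.00116 with an estimated correlation).

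Replication-dependent histone genes, made as cells copy their DNA, rose at 7 days (43 of 52 higher, median 1.31, adjusted p = 1.38e-33, 0.0299 with an estimated correlation) and 9 days (44 of 52 higher, median 1.22, adjusted p = 3.68e-37, 0.0299 with an estimated correlation), and at 5 days 36 of 52 higher (adjusted p = 0.241 with an estimated correlation). Proteasome subunits rose at 24 h (21 of 43 higher, median 0.43, adjusted p = 6.01e-11, 0.0429 with an estimated correlation) and 72 h (26 of 43 higher, median 0.47, adjusted p = 5.27e-13, 0.0299 with an estimated correlation), with the immunoproteasome genes Psmb9 (1.54 ± 0.23), Psmb8 (0.93 ± 0.21) and Psme1 (1.05 ± 0.15) at 24 h. Mitochondrial ribosomal proteins were higher at 24 h with the preset correlation (34 of 75 higher, median 0.40, adjusted p = 3.3e-14, 0.0599 with an estimated correlation). Immunoglobulin kappa variable genes were lower from 72 h to 5 days with the preset correlation (22 of 119 lower, median -0.75, adjusted p = 8.35e-24, 0.13 with an estimated correlation), and this family and the mitochondrial one were called in none of the 11 comparisons with an estimated correlation. Kappa medians against untreated were 0.60 after control ODN and 0.31 at 72 h, in the same run, and -0.46 at 5 days. The 5 day arrays lie outside that run, so run and time cannot be told apart.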
